A study of Mus musculus with 12 samples.

How the data were processed

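RNA from livers of male mice was measured on 12 two-colour Agilent whole-genome arrays, in 4 groups of 3 arrays: wild-type or Cyp1b1 null mice on a low-fat or a high-fat diet. Per the labels, each sample was set in Cy3 against a pool of wild-type low-fat liver in Cy5, with no dye swap, and each array carries a description of 3 pooled samples. Per the labels' protocols, RNA was isolated with a Qiagen kit and labelled with 1 of 2 Genisphere kits depending on its amount, and which kit each sample had is not given.

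The deposited intensity values of each spot are the mean pixel brightness and the median local background of both colours, made with Agilent's Feature Extraction under a protocol edited for local background (spot analysis 9.1.3.1), per the file headers. The processed intensities are background-subtracted and dye-normalised by the same software, per the file headers. The log10 ratios are of Cy5 over Cy3 from those processed signals, per the file headers. Marks for spots that are well above background, saturated or not uniform are deposited beside them. The authors' deposited table holds log2 ratios of group means per spot, made with limma per the submitters' processing notes, which give no version. Checked against the scanner files, that table equals the differences of group means of the log10 ratios, turned to log2 and to Cy3 over Cy5, on all 43379 spots within 1e-06, which settles its scale and direction.

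The values in the report were computed again from the spot intensities with limma 3.58.1 in R 4.3.3. Background was corrected by normexp with an offset of 50, log2 ratios of Cy3 over Cy5 were normalised within arrays by loess, and no normalisation between arrays was applied. The software's non-uniformity marks left out 120 spots over all arrays, and repeated spots of 245 probes were averaged. Of 41174 probes, 24844 were named through accessions, 6045 had a current symbol, 1810 an older symbol, and 8475 kept the name in the files. A fold given as at least N compares means of the sample channel after loess and Aquantile. The dimmer group is held at no less than the lowest signal well above background. Every sample was in Cy3, so a dye effect equal on all arrays cancels in this fold. No dyes were swapped, and a dye effect that differs between arrays would stay in it. A probe was measured when its sample channel was well above background on all 3 arrays of at least 1 group, which 21490 probes were, and a gene took its brightest measured probe. This gave 14911 genes, 4900 of them with several measured probes and 31 with a missing value. The sample channel was well above background on 18375 to 23439 probes per array and the reference on 17286 to 25998. Nothing is printed on genome positions, and each gene is identified by its symbol and, where it passed in a comparison of 3 against 3 arrays, its probe.

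Limma fitted 1 mean per group to all 12 arrays, which share 1 estimate of the spread (8 residual and 3.16 prior degrees of freedom), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The comparisons were null against wild-type at low fat and at high fat, high against low fat in wild-type and in null livers, and the interaction. The groups, these comparisons, the gene lists, the rule for named genes and most of the alternative settings were chosen before the data were examined. The mean of both diets, its named genes, the correlation of genotype differences and an alternative with scan as a block without wild-type low-fat array 1 were chosen after the data had been seen. The 32 gene lists cover lipid metabolism, nuclear receptor targets, sex-biased liver genes, inflammation, stress and cell type markers. They were tested with limma's camera with a preset correlation of 0.01, adjusted over the 32 lists and 5 comparisons, with an estimated correlation and limma's fry beside it. The mean of both diets was adjusted over its 32 lists alone.

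The named genes were Cyp1b1 and Nnt, in which C57BL/6J mice carry a deletion, in every comparison. To these came up to 8 rising and 8 falling genes with the largest change past the threshold whose arrays did not overlap between the groups, and 5 and 5 for the null diet response, the interaction and the mean of both diets. Names of clones, predicted genes and probes were passed over. For lists, up to 4 members past the threshold, or 2 with the smallest p where none passed, were named. Members were named only for lists that passed, a narrowing made after the data had been seen. Selected examples of these are printed.

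The steps were tested on simulated data with 14880 genes, made from each gene's mean and residual SD over all 12 arrays, with changes added to the null low-fat group. Of genes given a log2 change of 1, 47.8% (32 of 67) were recovered, of 2, 95.5% (64 of 67), and of 4, 100% (66 of 66). Of 169 genes called, 7 had not been changed, and 3 of 3 shifted lists were found. The simulated noise was independent between genes and between arrays and held no scan effect. It therefore checks the steps alone and gives no error rate for genes or lists on the real arrays. Replicate numbers were checked as pairs by the correlation of deviations from group means. In the wild-type diet comparison these were 0.329, 0.335 and 0.463, and same-numbered arrays share a scan, so the numbers pair the arrays there. In the other comparisons at least 1 pair was under 0.1.

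Alternatives were Agilent's processed signals, no background correction, median centring in place of loess, normalisation between arrays by Aquantile (which leaves log ratios as they are), the sample channel alone, other filters on dim probes, the mean of a gene's probes, a robust variance trend, array weights, the compared groups alone, blocks for replicate number, slide and scan, and each array left out in turn. The iteration for the array weights did not reach its tolerance. The authors' deposited table, without p-values, gave values alone. Correlations across genes were set against 100 draws of residuals permuted over all 12 arrays, without keeping the scans together, and intervals are at 95%. Figures were drawn with matplotlib 3.10.9.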

Results

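Gene expression was measured in livers of male mice on 12 two-colour Agilent arrays. The source label names liver hepatocytes, and every mouse was weaned at 3 weeks onto a diet with 10% or 60% of fat and killed at 14 weeks. The arrays form 4 groups of 3: wild-type low fat, wild-type high fat, Cyp1b1 null low fat and Cyp1b1 null high fat. Cyp1b1 encodes a cytochrome P450 that oxidises steroids, retinoids and polycyclic hydrocarbons. Each array set 1 sample, in Cy3, against pooled wild-type low-fat liver, in Cy5, and values are log2 ratios of sample over that reference. The sample channel was well above background on 18375 to 23439 of 41174 probes, and 14911 genes were tested. The number of arrays, 3 per group, limits the precision. The labels describe 3 pooled samples for each array without saying whether each replicate was its own pool of mice, so p-values measure the spread between these arrays. The arrays were read in 3 scans. Scan 3 held 2 wild-type arrays, 1 per diet, and no null array, so scan values are given beside the comparisons. Deviations from group means had a median r of 0.379 between arrays of different groups in the same scan, and -0.180 in different scans. The lowest r between log ratios of arrays of the same group was -0.085. The main fit has no term for scan, so its p-values leave this structure in the spread.

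The probe for Cyp1b1 (A_51_P255456) was brighter in the livers labelled null than in the wild-type livers. The log2 ratios were 1.68, 1.58 and 1.59 on the null low-fat arrays and 0.65, 1.68 and 1.23 on the null high-fat arrays. On the wild-type low-fat arrays they were 0.16, -0.85 and -1.11, and on the wild-type high-fat arrays -0.69, -0.13 and -0.88. The difference was 2.22 (SE 0.34) at low fat, with limma's adjusted p = 0.0765, and 1.75 (SE 0.34) at high fat, with adjusted p = 0.222. The first probe was well above background on 1 of the 3 wild-type low-fat arrays and on every array of the other groups, so the size of the low-fat difference depends on values near background. Agilent's processed signals gave 4.37 at low fat and 4.58 at high fat, so neither size is settled. A second Cyp1b1 probe (A_52_P297822) was well above background on 2 of the 12 arrays, both null. Whether the first probe lies in the deleted part of the gene is not given in the sources used here, so its signal does not check the labels, and null below means labelled null.

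The first question was how null livers differed from wild-type livers on the low-fat diet. C8b (A_51_P151214), which encodes a chain of complement component 8, rose by 1.42 on the log2 scale (SE 0.14). Its log2 ratio was 1.63 ± 0.10 (SD, n = 3) in null and 0.21 ± 0.02 (SD, n = 3) in wild-type livers. Moxd1 (A_51_P493987), a monooxygenase of the dopamine beta-hydroxylase family, rose by 3.39 (SE 0.42), from 0.15 ± 0.31 (SD, n = 3) to 3.54 ± 1.05 (SD, n = 3), and was well above background on 2 of the 3 wild-type arrays, so the size depends in part on a value near background. Cyp2a5 (A_52_P246252), the liver coumarin hydroxylase, fell by 2.25 (SE 0.26), from -0.20 ± 0.40 (SD, n = 3) to -2.45 ± 0.23 (SD, n = 3). For each of these 3 genes the null arrays did not overlap the wild-type arrays. Nnt, which encodes a mitochondrial transhydrogenase, differed by 0.25 (SE 0.17, adjusted p = 0.833).

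C8b (adjusted p = 0.00701), Moxd1 (0.0258) and Cyp2a5 (0.0245) were the 3 genes past limma's threshold, 2 higher and 1 lower. At an unadjusted p under 0.05 there were 1073 genes, 512 higher and 561 lower. Within scan 1, with 2 null arrays and 1 wild-type array, the differences were 1.46 for C8b, 3.05 for Moxd1 and -2.44 for Cyp2a5. These null arrays were on slide 1 and the wild-type array was on slide 2. Slide and genotype therefore cannot be told apart in any low-fat genotype value within scan 1. Within scan 2, with 1 array each, they were 1.38, 4.11 and -1.57. With scan as a block, 14 genes passed, C8b (adjusted p = 0.0105), Moxd1 (0.0105) and Cyp2a5 (0.0455) among them. Agilent's processed signals gave 51 genes, 21 higher and 30 lower, while median centring in place of loess, a robust variance trend, and a fit of these 2 groups alone gave 0. The count was 13 without wild-type low-fat array 1, 26 without wild-type low-fat array 2, and 1 without wild-type high-fat array 3, null low-fat array 2, null high-fat array 1 or null high-fat array 3. C8b passed without any 1 array but not in the sample channel alone. Moxd1 did not pass without wild-type low-fat array 3, any 1 wild-type high-fat array, null low-fat array 2 or null high-fat array 1 or 3. Cyp2a5 did not pass without wild-type low-fat array 3, wild-type high-fat array 3, null low-fat array 2 or 3 or null high-fat array 1 or 3.

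Genes that are more abundant in male than in female mouse liver were higher as a group in the null livers at low fat. Of 28 measured members 27 were higher, with a median change of 1.10 (camera adjusted p = 8.06e-19, and adjusted p = 0.0412 with an estimated correlation). C8b and Moxd1 passed over all genes, and 11 members passed when adjusted over the list alone. The list's median was 1.57 within scan 1 and 0.69 within scan 2, and 1.07 with scan as a block, where its call was kept with the preset correlation and lost with an estimated correlation (adjusted p = 0.139). On wild-type low-fat array 1 the median of this list lay -0.52 from the mean of the other 2 wild-type low-fat arrays, and without it the list's median was 0.61. Female-biased liver genes were lower as a group, 22 of 29, with a median of -0.48 (camera adjusted p = 5.39e-08, and adjusted p = 0.20 with an estimated correlation). None passed over all genes, and 11 lower and 1 higher member passed adjusted over the list alone. Examples were Cyp2a4, a steroid hydroxylase, at -2.43 (SE 0.48, adjusted p = 0.147) and Cyp4a14, a fatty acid omega-hydroxylase that is also a PPARalpha target, at -5.08 (SE 0.77, adjusted p = 0.0765).

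Targets of PPARalpha, the fatty acid receptor that drives fat oxidation in liver, were lower at low fat in 23 of 27 measured members. The median was -0.82 (camera adjusted p = 5.65e-12, and adjusted p = 0.140 with an estimated correlation). It was -0.59 within scan 1, -1.01 within scan 2 and -0.85 with scan as a block. None of the members passed over all genes, and 9 passed, all lower, adjusted over the list alone. Cyp4a10, another fatty acid omega-hydroxylase, stood at -3.44 (SE 0.48, adjusted p = 0.0614). PPARgamma targets and lipid droplet genes were lower in 20 of 23, with a median of -0.62 (camera adjusted p = 2.16e-06, and adjusted p = 0.142 with an estimated correlation), and 3 passed adjusted over the list alone. Pparg itself, a regulator of fat storage, was at -1.99 (SE 0.30, adjusted p = 0.0765), and Hilpda, a lipid droplet protein, at -1.29 (SE 0.27, adjusted p = 0.196). NRF2 targets had a median of -0.58, with 17 of 23 lower (camera adjusted p = 0.000521, and adjusted p = 0.114 with an estimated correlation). Gsta2, a glutathione transferase, was at -2.32 (SE 0.48, adjusted p = 0.190). CAR and PXR targets, with Cyp2a5 among them, were lower in 16 of 21, with a median of -0.33 (camera adjusted p = 0.00521, and adjusted p = 0.480 with an estimated correlation). Mitochondrial and peroxisomal fatty acid oxidation had a median of -0.16, with 19 of 26 lower (camera adjusted p = 0.0125, and adjusted p = 0.20 with an estimated correlation). Genes of the unfolded protein and integrated stress response were higher in 21 of 28, with a median of 0.42 (camera adjusted p = 0.00954, and adjusted p = 0.537 with an estimated correlation).

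Markers of other cells and of division also passed as lower lists at low fat with the preset correlation. Kupffer cell and macrophage markers had a median of -0.36, with 22 of 24 lower (adjusted p = 0.0110, and adjusted p = 0.647 with an estimated correlation). The cell cycle list had -0.47, with 26 of 27 lower (adjusted p = 0.000382, and adjusted p = 0.570 with an estimated correlation). Stellate cell and fibrosis markers had -0.32, with 18 of 21 lower (adjusted p = 0.0372, and adjusted p = 0.700 with an estimated correlation). Wild-type low-fat array 1 stood above the mean of the other 2 arrays of its group by 1.23 in the Kupffer list, 1.01 in the cell cycle list and 1.24 in the stellate list, and without it these lists lost their calls, with medians of 0.02, -0.06 and 0.07. Within scan 2, which does not hold that array, their medians were 0.50, 0.63 and 0.13, opposite to the reported direction. Bile duct markers were lower in 13 of 13, with a median of -0.24 (adjusted p = 0.00535, and adjusted p = 0.553 with an estimated correlation). MHC genes had a median of -0.34 and lymphocyte markers -0.17 (adjusted p = 0.420 and 0.452 with an estimated correlation). Cytokines and chemokines had -0.31 (adjusted p = 0.641 with an estimated correlation), and 0.44 within scan 2. On wild-type low-fat array 1 the bile duct, MHC and cytokine medians were 0.09, 0.27 and -0.06, each the highest of its group, and without it these lists and CAR and PXR targets lost their calls. In all, 15 of 32 lists passed at low fat, 2 higher and 13 lower. Of these, 1 held with an estimated correlation, 1 passed fry's test of movement in one direction, and 10 lists passed without wild-type low-fat array 1.

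The next question was how null livers differed from wild-type livers on the high-fat diet. C8b rose by 1.42 (SE 0.14), from 0.07 ± 0.01 (SD, n = 3) to 1.49 ± 0.20 (SD, n = 3), and Moxd1 rose by 3.42 (SE 0.42), from -0.05 ± 0.08 (SD, n = 3) to 3.37 ± 0.39 (SD, n = 3). Moxd1 was well above background on 1 of the 3 wild-type arrays, so the size of its change depends on values near background. These were the genes past limma's threshold, with adjusted p = 0.00680 for C8b and 0.0350 for Moxd1, and neither overlapped between the groups. Cyp4a14 stood at -5.41 (SE 0.77, adjusted p = 0.0909), Cyp4a10 at -3.29 (SE 0.48, adjusted p = 0.0909) and Scd1, the desaturase that makes monounsaturated fatty acids, at -2.85 (SE 0.48, adjusted p = 0.101). Nnt differed by 0.80 (SE 0.17, adjusted p = 0.335).

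At high fat 383 genes had an unadjusted p under 0.05, 184 higher and 199 lower. Within scan 1, with 2 null arrays and 1 wild-type array, C8b differed by 1.53 and Moxd1 by 3.17. Within scan 2, with 1 array each, they differed by 1.23 and 3.81. With scan as a block, 5 genes passed, with adjusted p = 0.0123 for both C8b and Moxd1. Agilent's processed signals gave 50 genes, 19 higher and 31 lower, while median centring and a robust variance trend gave 0. The count was 0 without any 1 of the wild-type high-fat arrays, null high-fat array 1 or null high-fat array 3, 1 without null high-fat array 2 or null low-fat array 2, and 5 without wild-type low-fat array 2 or 3. Without wild-type low-fat array 1 Moxd1 no longer passed, with the change still 3.42. C8b did not pass in the sample channel alone or in a fit of these 2 groups.

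Male-biased genes were higher at high fat in 26 of 28 members, with a median of 0.68 (camera adjusted p = 8.06e-19, and adjusted p = 0.0412 with an estimated correlation). C8b and Moxd1 passed over all genes and 8 members adjusted over the list alone. The median was 0.62 within scan 1, 0.73 within scan 2 and 0.74 with scan as a block, where an estimated correlation gave adjusted p = 0.137. Female-biased genes were lower in 24 of 29, with a median of -0.48 (camera adjusted p = 7.67e-15, and adjusted p = 0.104 with an estimated correlation), and 1 member, Cyp4a14, passed adjusted over the list alone. PPARalpha targets were lower in 25 of 27, with a median of -0.73 (camera adjusted p = 1.96e-23, and adjusted p = 0.0533 with an estimated correlation). Their median was -0.85 within scan 1, -0.70 within scan 2 and -0.77 with scan as a block, and 8 members passed, all lower, adjusted over the list alone. Fatty acid oxidation genes were lower in 23 of 26, with a median of -0.36 (camera adjusted p = 4.36e-07, and adjusted p = 0.0412 with an estimated correlation). Examples were Crat at -1.23 (SE 0.42) and Ech1 at -0.61 (SE 0.20). That list's median was -0.33 with scan as a block, where an estimated correlation gave adjusted p = 0.137, and -0.23 without wild-type high-fat array 1. PPARgamma targets and lipid droplet genes had a median of -0.57, with 19 of 23 lower (camera adjusted p = 4.00e-09, and adjusted p = 0.104 with an estimated correlation). CAR and PXR targets were lower in 21 of 21, with a median of -0.49 (camera adjusted p = 3.67e-10, and adjusted p = 0.114 with an estimated correlation).

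Lipid synthesis genes were also lower as lists at high fat. Cholesterol synthesis had a median of -0.41, with 21 of 26 lower (camera adjusted p = 6.98e-10, and adjusted p = 0.142 with an estimated correlation). The median was -0.71 within scan 1 and -0.18 within scan 2. On wild-type high-fat array 1 it was 0.54, against -0.080 and 0.053 on the other arrays of that group, and without that array the list kept its call with a median of -0.20. Its leading member Hmgcs1, which makes HMG-CoA, was at -1.68 (SE 0.32, adjusted p = 0.222), but Agilent's processed signals turned its sign (1.90). Fatty acid and triglyceride synthesis had a median of -0.08, with 16 of 28 lower (camera adjusted p = 0.0380, and adjusted p = 0.700 with an estimated correlation). Scd1 and Me1, the malic enzyme that supplies NADPH, passed adjusted over that list alone, Me1 at -2.49 (SE 0.57, adjusted p = 0.461 over all genes). Without wild-type high-fat array 1 that list's test turned upward, with a median of 0.20. Oxidative phosphorylation had a median of -0.27 (adjusted p = 0.260 with an estimated correlation), NRF2 targets -0.24 (adjusted p = 0.140), adipocyte markers -0.52 (adjusted p = 0.140), interferon-stimulated genes -0.22 (adjusted p = 0.287), MHC genes -0.23 (adjusted p = 0.568) and retinoid metabolism -0.13 (adjusted p = 0.195), each lower with the preset correlation. Of the adipocyte markers, Cfd was not well above background on any null high-fat array and was at least 12.3-fold lower there than in wild-type high-fat livers (adjusted p = 1.00). The acute phase response, at 0.24, and the unfolded protein response, at 0.11, were higher with the preset correlation (adjusted p = 0.657 and 0.570 with an estimated correlation), and the latter was at -0.073 within scan 2. In all, 16 of 32 lists passed at high fat, 3 higher and 13 lower, of which 2 held with an estimated correlation and 0 passed fry's directional test.

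C8b and Moxd1 were the genes higher in null livers in both diets, against 0.000268 shared genes from independent lists of this size. The lists are not independent, since the diets share the common reference and the estimate of spread from all 12 arrays, though no array of a group, so no p-value is given. At an unadjusted p under 0.05, 92 genes were higher in both diets and 94 lower in both, against 6.32 and 7.49 from independent lists. Genes are not independent replicates, and both comparisons share the same imbalance of scans. No gene remained shared with median centring, a robust variance trend, or without any 1 of the wild-type high-fat arrays, null high-fat array 1 or null high-fat array 3, 1 was shared without null low-fat array 2 or null high-fat array 2, and 4 without wild-type low-fat array 2.

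**Figure D1:**
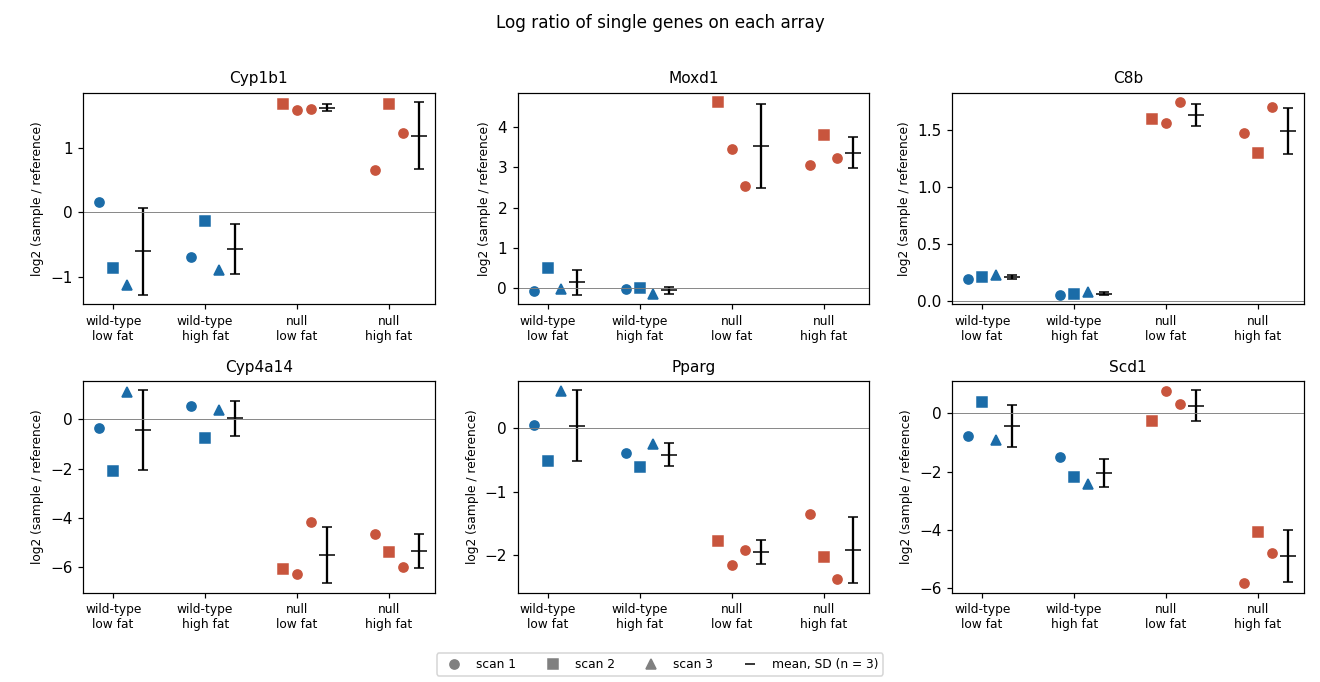
Log2 ratio of sample over reference for 6 genes on each of the 12 arrays, by group, with the marker shape giving the scan and the bar the mean and SD of 3 arrays. C8b, Moxd1 and Cyp1b1 lie higher on all 6 null arrays than on all 6 wild-type arrays, Cyp4a14 and Pparg lie lower, and Scd1 reaches -4.89 ± 0.88 (SD) in null high-fat livers.

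**Figure D2:**
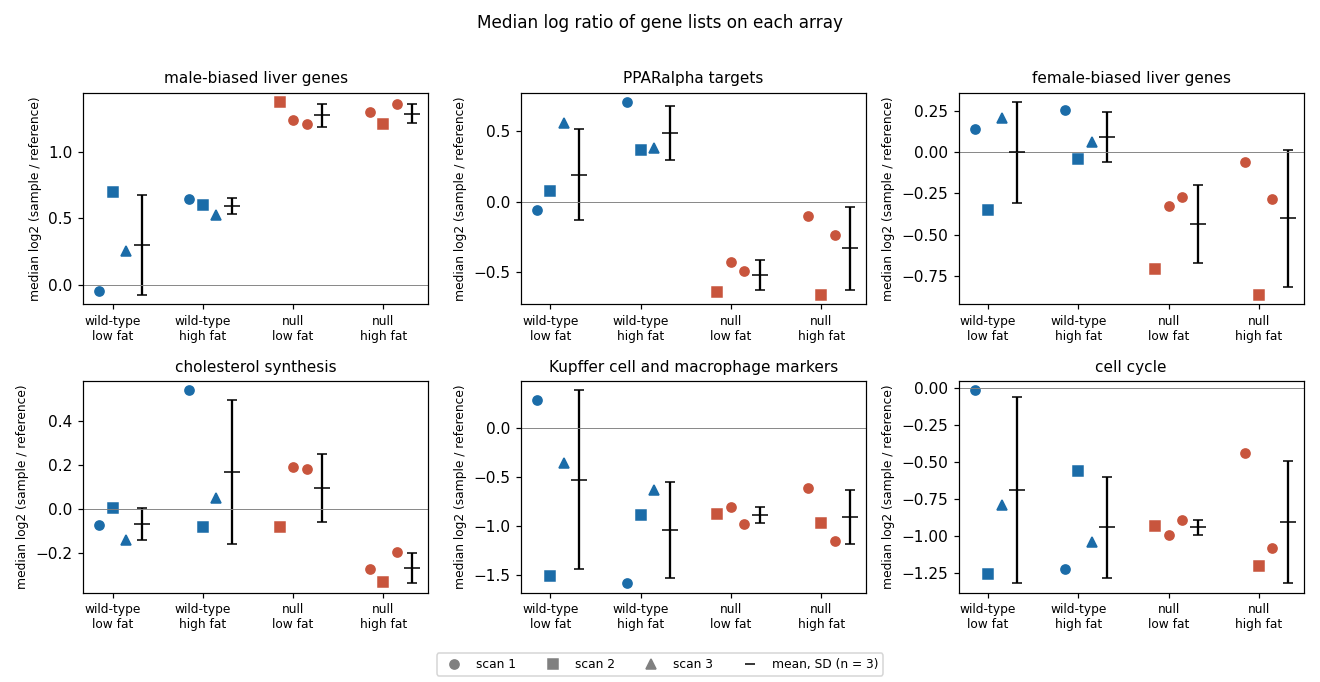
Median log2 ratio of sample over reference over the measured members of 6 gene lists on each of the 12 arrays, by group, with the marker shape giving the scan and the bar the mean and SD of 3 arrays. The male-biased list lies between 1.21 and 1.37 on the null arrays and between -0.05 and 0.70 on the wild-type arrays, and wild-type low-fat array 1 has the highest Kupffer median (0.29).

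Averaging the genotype difference over both diets, a comparison added after the single-diet counts had been seen, gave more genes past the threshold. Cyp4a14 fell by 5.24 (SE 0.55), from -0.19 ± 1.15 (SD, n = 6) in wild-type to -5.44 ± 0.85 (SD, n = 6) in null livers, and Cyp4a10 fell by 3.36 (SE 0.34), from 0.59 ± 0.83 to -2.77 ± 0.60 (SD, n = 6). Pparg fell by 1.74 (SE 0.21), from -0.19 ± 0.45 to -1.94 ± 0.35 (SD, n = 6). Moxd1 rose by 3.40 (SE 0.30), Lifr, the receptor for leukaemia inhibitory factor, by 1.86 (SE 0.20), Cyp2c70, which makes mouse muricholic acids, by 1.48 (SE 0.19) and C8b by 1.42 (SE 0.10). Cyp1b1 rose by 1.99 (SE 0.24), and Nnt was at 0.53 (SE 0.12, adjusted p = 0.156). Apart from Nnt, which was named whatever its values, these genes were higher, or lower, on all 6 null arrays than on all 6 wild-type arrays.

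Limma's adjusted p was 0.00297 for Cyp4a14, 0.00288 for Cyp4a10, 0.00561 for Pparg, 0.00113 for Moxd1, 0.00320 for Lifr, 0.00580 for Cyp2c70, 0.000185 for C8b and 0.00561 for Cyp1b1. In all, 43 genes passed, 24 higher and 19 lower, against 1252 at an unadjusted p under 0.05. Other genes that fell were Vnn1, which encodes pantetheinase, at -2.45, Lgals1, the lectin galectin-1, at -2.16, Acot1, an acyl-CoA thioesterase, at -2.01, Cyp2a4 at -1.96, Cyp2a5 at -1.94, Gstt3, a glutathione transferase, at -1.49 and Ddah1, which degrades methylarginines, at -1.33. Others that rose were Fam160b1 at 1.38 and Egfr, the epidermal growth factor receptor, at 1.38. Selenbp2 (adjusted p = 0.0262) was saturated on all 6 null arrays and was at least 1.75-fold higher there. With scan as a block 94 genes passed, and the adjusted p was 0.00495 for Cyp4a14 and 0.0162 for Pparg, while Cyp2a4 no longer passed (adjusted p = 0.0667). With slide as a block the count fell to 11, and slide 1 held null arrays alone and slide 4 wild-type arrays alone. It fell to 25 with replicate number as a block, 21 with a robust variance trend and 23 with no filter on dim probes. Blocks thus moved the count both ways. The count was 237, 99 higher and 138 lower, from Agilent's processed signals, 113, 46 higher and 67 lower, without background correction, and 1 with median centring. It was 113 without wild-type low-fat array 1, 70 without wild-type low-fat array 2, between 19 and 24 without wild-type low-fat array 3, any 1 wild-type high-fat array, null low-fat array 2, null low-fat array 3 or null high-fat array 3, and at least 30 otherwise. Cyp2a4 and Egfr each lost their call in 10 of the 12 fits with 1 array left out, Ddah1 in 7, Selenbp2 in 6 and Vnn1 in 6, and the other genes named here in 0.

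As lists over both diets, male-biased genes were higher in 27 of 28, with a median of 0.98 (0.55 without wild-type low-fat array 1), and 5 passed over all genes, C8b, Egfr, Moxd1 and Selenbp2 among them (13 adjusted over the list alone). PPARalpha targets were lower in 26 of 27, with a median of -0.64. Acot1, Cyp4a10, Cyp4a14 and Vnn1 were among the 5 that passed over all genes, and 15 passed adjusted over the list alone. Female-biased genes had a median of -0.48, PPARgamma targets and lipid droplet genes -0.56, NRF2 targets -0.30 and fatty acid oxidation -0.26. With an estimated correlation these 6 of 16 passing lists held, with camera's adjusted p = 0.0231 for male-biased genes, 0.0348 for PPARalpha targets, 0.0495 for female-biased genes, 0.0356 for PPARgamma targets, 0.0348 for NRF2 targets and 0.0348 for fatty acid oxidation. With scan as a block as well, the adjusted p was 0.0489 for male-biased genes, PPARalpha targets, female-biased genes and NRF2 targets, 0.155 for PPARgamma targets and 0.0655 for fatty acid oxidation. Adipocyte markers were lower in 7 of 7, with a median of -0.47 (camera adjusted p = 0.0152, and adjusted p = 0.103 with an estimated correlation). They share Cfd, Cidec, Fabp4, Lipe and Pnpla2 with the PPARgamma list, and their call was lost with scan as a block (adjusted p = 0.0662) and without wild-type low-fat array 1 (median -0.20). Fry's directional test passed 8 lists, and the 10 lists beyond those 6 that passed camera with the preset correlation had adjusted p from 0.103 to 0.648 with an estimated correlation.

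The question of diet was asked in wild-type livers. Cd9 (A_51_P320852), which encodes a tetraspanin of the cell surface, fell by 1.83 at high fat (SE 0.21), from -0.59 ± 0.43 (SD, n = 3) to -2.42 ± 0.11 (SD, n = 3). It was the gene that passed limma's threshold, with adjusted p = 0.0316, and at an unadjusted p under 0.05 there were 601 genes, 271 higher and 330 lower. Cyp1b1 differed by 0.04 (SE 0.34) and Nnt by 0.01 (SE 0.17). Scd1 was at -1.59 (SE 0.48, adjusted p = 0.897). Cd9 differed by -2.44 within scan 1, -1.57 within scan 2 and -1.48 within scan 3, with 1 array per diet each. With the replicate number as a block, 0 genes passed and Cd9 had adjusted p = 0.0885. That number is the scan for the wild-type arrays but not for the null arrays in the same fit, so this p is not from a test paired by scan. With scan as a block, 0 genes passed as well. The adjusted p of 0.0316 for Cd9 is from the fit without a term for scan, although the wild-type arrays are paired by scan. No gene passed without any 1 array other than wild-type low-fat array 1, nor with median centring, a robust variance trend, no filter on dim probes or the 2 groups alone, and 5 passed, 0 higher, with Agilent's processed signals.

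Fatty acid oxidation genes were higher at high fat in 23 of 26 members in wild-type livers, with a median of 0.38 (camera adjusted p = 9.53e-07, and adjusted p = 0.0412 with an estimated correlation). Decr2, a peroxisomal dienoyl-CoA reductase, was at 0.70 (SE 0.14, adjusted p = 0.585) and passed adjusted over the list alone. The list's median was 0.45, 0.49 and 0.08 within the 3 scans, and with scan as a block and an estimated correlation the adjusted p = 0.137. Bile acid synthesis and transport had a median of 0.48, with 24 of 28 higher (camera adjusted p = 4.48e-08, and adjusted p = 0.260 with an estimated correlation), and Cyp27a1, which starts the acidic pathway, was at 0.94 (SE 0.25). CAR and PXR targets were higher in 16 of 21, with a median of 0.66 (camera adjusted p = 5.23e-06, and adjusted p = 0.20 with an estimated correlation). Cyp2c54 stood at 2.50 (SE 0.61) and Cyp2a5 at 1.07 (SE 0.26). Circadian clock outputs had a median of 0.47, with Dbp at 1.73 (SE 0.44) and Tef at 1.62 (SE 0.44) (adjusted p = 0.420 with an estimated correlation). PPARalpha targets had a median of 0.32, male-biased genes 0.29 and cholesterol synthesis 0.16 (adjusted p = 0.570, 0.452 and 0.553 with an estimated correlation). Within scans 1, 2 and 3 the medians were 0.64, 0.20 and -0.23 for PPARalpha targets, 0.57, -0.019 and 0.24 for male-biased genes, and 0.64, -0.069 and 0.21 for cholesterol synthesis, so each changed direction in 1 scan.

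Kupffer cell and macrophage markers were lower at high fat in 23 of 24 members in wild-type livers, with a median of -0.43 (adjusted p = 0.547 with an estimated correlation). The cell cycle list had a median of -0.35 and the acute phase response -0.44 (adjusted p = 0.553 for both with an estimated correlation). Wild-type low-fat array 1 stood above the other 2 low-fat arrays by 1.23, 1.01 and 1.08 in these 3 lists, and the Kupffer median was -1.78 within scan 1, 0.62 within scan 2 and -0.05 within scan 3. Within scan 2 the cell cycle list was at 0.43, the acute phase response at 0.20, cytokines at 0.40, NRF2 targets at 0.13 and lymphocyte markers at 0.052, and within scan 3 bile duct markers were at 0.20, all opposite to their overall medians. Fatty acid and triglyceride synthesis had a median of -0.34, with 20 of 28 lower (adjusted p = 0.595 with an estimated correlation), and 0.36 within scan 1. NRF2 targets had -0.17, with G6pdx, the first enzyme of the pentose phosphate pathway, at -1.68 (SE 0.35), and adjusted p = 0.195 with an estimated correlation. PPARgamma targets had -0.14, bile duct markers -0.25, cytokines -0.24, MHC genes -0.18 and lymphocyte markers -0.09 (adjusted p = 0.452, 0.572, 0.580, 0.537 and 0.516 with an estimated correlation). In all, 17 of 32 lists passed with the preset correlation, 7 higher and 10 lower, 17 with the replicate block, 9 without wild-type low-fat array 1 and 10 without wild-type high-fat array 1. With an estimated correlation 1 held, and 0 passed fry's directional test.

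In null livers, Scd1 (A_52_P682382) fell by 5.14 at high fat (SE 0.48), from 0.26 ± 0.52 (SD, n = 3) to -4.89 ± 0.88 (SD, n = 3). It was the gene that passed limma's threshold, with adjusted p = 0.00453, and 284 genes had an unadjusted p under 0.05. Genes of fatty acid and triglyceride synthesis, Scd1 among them, were lower in 20 of 28, with a median of -0.58 (camera adjusted p = 5.83e-15, and adjusted p = 0.20 with an estimated correlation). Scd1 passed over all genes, and 6 members passed, all lower, adjusted over the list alone. Cyp1b1 differed by -0.43 (SE 0.34) and Nnt by 0.56 (SE 0.17, adjusted p = 1.00). Scd1 differed by -5.82 within scan 1 and -3.78 within scan 2, and with scan as a block its adjusted p was 0.0110. In scan 1 the null low-fat arrays were on slide 1 and the null high-fat arrays on slide 2, so slide and diet cannot be told apart there. No gene passed without null low-fat array 3 or with median centring.

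Cholesterol synthesis was lower in null livers at high fat in 19 of 26, with a median of -0.23 (camera adjusted p = 1.70e-06, and adjusted p = 0.244 with an estimated correlation). Fatty acid oxidation was higher in 21 of 26, with a median of 0.27 (camera adjusted p = 1.72e-05, and adjusted p = 0.0533 with an estimated correlation), and Decr2 was at 0.80 (SE 0.14, adjusted p = 0.402). CAR and PXR targets had a median of 0.31, with Cyp2a5 at 1.70 (SE 0.26, adjusted p = 0.354), PPARalpha targets 0.25 and bile acid genes 0.19 (adjusted p = 0.317, 0.553 and 0.570 with an estimated correlation). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at 1.55 (SE 0.60, adjusted p = 1.00). The acute phase response had a median of -0.31 and PPARgamma targets -0.05 (adjusted p = 0.553 and 0.537 with an estimated correlation). Within scan 1, with 2 arrays per diet, these medians were 0.19 and 0.056, and within scan 2, with 1 array each, -0.94 and -0.25. The acute phase median was 0.18 on null low-fat array 1, against -0.88 and -0.34 on the other arrays of that group. Without that array both lists lost their calls, with medians of -0.018 and -0.013, and both also lost them without null high-fat array 2. In all, 8 of 32 lists passed with the preset correlation, 4 higher and 4 lower, and 4 passed without null low-fat array 1. With an estimated correlation 0 held, and fry's directional test passed 0.

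The interaction asked whether the genotype difference at high fat differed from that at low fat. No gene passed in limma, 134 had an unadjusted p under 0.05, and the smallest adjusted p was 1.00. For Scd1 the difference was -3.55 (SE 0.67, adjusted p = 1.00 over all genes), and Scd1 passed adjusted over the list of fatty acid and triglyceride synthesis alone (adjusted p = 0.00713). Cyp1b1 had -0.47 (SE 0.48) and Nnt 0.55 (SE 0.25). Of the lists, cholesterol synthesis was lower in 22 of 26 members, with a median of -0.56 (camera adjusted p = 1.12e-10, and adjusted p = 0.140 with an estimated correlation). Idi1, an isomerase of that pathway, was at -1.30 (SE 0.43). In all, 13 of 32 lists passed with the preset correlation, 5 higher and 8 lower, and 7 passed without wild-type low-fat array 1 and 6 without wild-type high-fat array 1. With an estimated correlation 0 held, and 0 passed fry's directional test.

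Across genes, the diet responses of null and wild-type livers correlated with r = 0.358 (Spearman's rho = 0.277), and r was 0.0200 within scan 1 and -0.0059 within scan 2. The genotype differences at low and high fat correlated with r = 0.553 (rho = 0.466), and r was -0.0457 within scan 1 and 0.297 within scan 2. The diets share no arrays, and 95% of 100 draws of permuted residuals gave r from -0.641 to 0.704 for the first and from -0.703 to 0.733 for the second. The draws permuted residuals over all 12 arrays without keeping the scans together, so these ranges include differences between scans. The correlation of genotype effect at high fat with diet response in wild-type livers involves shared wild-type high-fat arrays, and its r was -0.0704 (rho = -0.0893) where draws without an effect gave a mean of -0.535 and a range of -0.941 to 0.0698, which contains it. The covariance was -0.00579 against a simulated -0.0582, with a range of -0.178 to 0.00429. The value was -0.427 within scan 1 and -0.284 within scan 2, 0.0583 with scan as a block, 0.0649 with slide as a block, 0.0800 without wild-type low-fat array 1 and 0.0681 without null high-fat array 1. The genotype difference at low fat and the diet response in wild-type livers share the wild-type low-fat arrays. Their r was 0.521 (rho = 0.517), 0.798 within scan 1 and 0.637 within scan 2, where draws gave a mean of 0.421 and a range of -0.403 to 0.873, which contains it. The covariance was 0.0567 against a simulated 0.0478, with a range of -0.0180 to 0.157. Part of both correlations with shared arrays may come from those arrays. Genes are not independent replicates, and these were 4 relations of 1 family with no p-value.

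The authors' deposited table held log2 ratios of group means per spot, with no p-values. Over the 14911 genes, its values correlated with those above with r = 0.822 for genotype at low fat, 0.766 for genotype at high fat and 0.739 for diet in wild-type livers. Among genes over 2-fold in the fit, the signs were alike for 100% of 307, 99.3% of 148 and 100% of 166. Both sets of values come from the same arrays, and these genes were picked for a large change there. The likeness is therefore no independent support. In the authors' deposited table C8b was at 1.54 at low fat and 1.44 at high fat, Moxd1 at 3.42 and 4.24, Cyp1b1 at 4.37 and 4.58, and Cd9 at -2.09 for diet in wild-type livers.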

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

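Tests chosen only after the result was seen are those of scan and of wild-type low-fat array 1 for both list patterns, and those of a female liver and of the scan for wild-type low-fat array 1, while the tests of the reference channel and of other cell types were chosen before.

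These 13 lists differed between the diets in their genotype difference, by camera's test of the interaction with the preset correlation, and 0 of them passed with an estimated correlation. Kupffer cell and macrophage markers had a median interaction of 0.56 (adjusted p = 0.553 with an estimated correlation). The cell cycle list had 0.45 (0.553), bile duct markers 0.43 (0.537), MHC genes 0.23 (0.561) and lymphocyte markers 0.13 (0.480). Cholesterol synthesis had -0.56 (0.140), fatty acid and triglyceride synthesis -0.30 (0.553), glucose production and insulin signalling -0.19 (0.179) and male-biased genes -0.14 (0.452). Bile acid genes had -0.13 (0.553), oxidative phosphorylation -0.13 (0.570), retinoid metabolism -0.084 (0.295) and the circadian clock -0.083 (0.570). Without wild-type low-fat array 1, 7 lists passed, and without wild-type high-fat array 1, 6 passed. That low-fat array stood above the other 2 of its group by 1.23 in the Kupffer list and 1.01 in the cell cycle list. Over the 27 alternative settings the lowest medians were 0.024 for Kupffer markers, 0.035 for the cell cycle and 0.076 for bile duct markers. Cholesterol synthesis stayed between -0.87 and -0.30.

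PPARalpha targets were lower in null livers in both diets. With scan as a block, the list stayed past the threshold over both diets with an estimated correlation (adjusted p = 0.0489), and within scan 2 its medians were -1.01 at low fat and -0.70 at high fat. That p is close to 0.05, and in the single diets the blocked p was 0.139 and 0.111, so the imbalance of scans is argued against as the whole cause and no further. Without wild-type low-fat array 1 the median at low fat was -0.74 (95% interval over genes -1.15 to -0.36). In the sample channel alone the medians of the 2 diets were -0.68 (-1.05 to -0.27) for the one nearer 0 and -0.76 for the other. The sample-channel values argue against the reference as the source. On wild-type low-fat array 1 the list's median was -0.06, against 0.08 and 0.56 on the other arrays of its group. That array was thus the nearest of its group to the null arrays. Leaving it out could hardly have removed the fall and decides nothing on that array, which also does not enter the high-fat medians. The genotype and anything that differs with it, such as the animals' breeding, stay open, untested.

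Male-biased genes were higher in null livers in both diets. With scan as a block, the adjusted p was 0.0489 over both diets with an estimated correlation, and the medians within scan 2 were 0.69 and 0.73, while in the single diets the blocked p was 0.139 and 0.137. Without wild-type low-fat array 1 the median at low fat was 0.61 (95% interval over genes 0.27 to 1.35), against 1.10 with it. In the sample channel alone the medians were 0.87 at low fat and 0.50 (0.20 to 0.95) at high fat. These values argue against that array or the reference as the whole source. The blocked p over both diets is close to 0.05, comes from a comparison added after the data were seen, and was not matched in the single diets. The medians within scan 2 rest on 1 array per group. The imbalance of scans is therefore argued against as the whole cause and no further. Genotype and breeding both stay open, untested.

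Male-biased genes were low on wild-type low-fat array 1, with a list median of -0.05 against 0.70 and 0.25 on the other arrays of its group. A female liver is argued against by 3 of 3 probes of Ddx3y and Eif2s3y, on the Y chromosome, well above background there and 0 of 4 of Xist. Hepatocyte secreted proteins differed by 0.16 (95% interval over genes -0.30 to 0.60) while male-biased genes differed by -0.52, which met the criterion set beforehand against RNA from other cells. However, the hepatocyte median ran from -0.26 to 0.56 between wild-type high-fat arrays, and the interval is over genes, not arrays. Kupffer, stellate and endothelial markers were higher by 1.23, 1.24 and 0.58. These values therefore cannot decide on RNA from other cells. The lowest of the other arrays of scan 1 had 0.65, but none of these is wild-type low fat, so that value excludes nothing, while within the other groups scan 1 differed from scan 2 by -0.15 to 0.12, against -0.75 in this group, which argues against a scan effect shared by all groups. A scan effect in this group alone and RNA from other cells stay open, and beyond sex and RNA from other cells no biological explanation was tested.

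Other splits of the arrays were counted for each comparison. For 3 against 3 arrays there are 10 splits, too few for a share under 0.05. At low fat the real split gave 3 genes and 15 lists and the highest other 0 and 12, with 1 of 10 splits as high for each. At high fat these were 2 genes and 16 lists against 0 and 13, again 1 of 10 each, and for diet in wild-type livers 1 gene and 17 lists against 0 and 15, 1 of 10 each. For diet in null livers they were 1 gene against 0 (1 of 10) and 8 lists against 13 (4 of 10). For the interaction, limma gave 0 genes, with 134 at an unadjusted p under 0.05. All 100 splits drawn reach a count of 0 whatever the data, so that count tests nothing. The 13 lists were reached by 19 of 100 splits, with a highest of 20, so chance cannot be excluded for the lists. The highest split for genes, 2752 genes, follows the scans exactly and points to a structure of the samples by scan, and with scan as a block the real count was 0. For the mean of both diets 2 of 100 splits gave as many genes as the real 43, a share under 0.05. These splits do not keep the scans together and the comparison was added after the single-diet counts were seen, so chance is excluded only for splits that ignore the scans. The highest other, 849 genes, put 5 of its 6 arrays from scan 1 on the same side, which points to the same structure. With scan as a block the real count was 94, and with slide as a block it was 11. For its 16 lists 9 of 100 splits gave as many, with a highest of 20, so chance cannot be excluded for that count.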

How the results depend on the processing

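The tests of the mean of both diets and of scan as a block without wild-type low-fat array 1 were chosen after the results were seen. Counts of genes are given in the order low-fat genotype, high-fat genotype, wild-type diet, null diet, mean of both diets and both diets shared, where the reported values are 3, 2, 1, 1, 43 and 2, and a count not given stayed within 1.5 times. Without background correction they were 11 (5 higher and 6 lower), 10 (5 and 5), 2, same, 113 and 6, with Cyp1b1 at 2.39 and 2.57 in the 2 genotype comparisons, and with Cyp1b1 at -0.34 for wild-type diet and 0.18 for the interaction. With median centring they were 0, 0, 0, 0, 1 and 0. That setting moved the median of all genes to 0.33 at low fat, 0.13 for wild-type diet, -0.21 for the interaction and 0.21 for the mean, and turned Cyp1b1 for wild-type diet (-0.021), the oxidative phosphorylation list (0.27) and Ndufs4 (0.073) in the mean. In the sample channel alone they were 49, 61, 11, 4, 319 and 24, the 49 as 21 higher and 28 lower, the 61 as 26 and 35, the 4 as 3 and 1, and the 319 as 138 and 181, with Cyp1b1 at 2.28 and 2.60. There Tagln at low fat (0.052), Cyp1b1 for wild-type diet (-0.25), null diet (0.069) and interaction (0.32), Serpina3k for null diet (0.0069) and Ndufv1 for the interaction (0.085) turned. Agilent's processed signals gave 51, 50, 5, same, 237 and 22, with Cyp1b1 at 4.37 and 4.58, and turned Hmgcs1 at high fat (1.90) and in the mean (0.72), Cyp1b1 for wild-type diet (-0.32) and interaction (0.21), and Nnt for wild-type diet (-0.034). The authors' deposited table gave 1.90, -0.32 and -0.034 for Hmgcs1 at high fat and for Cyp1b1 and Nnt for wild-type diet. With no filter on dim probes the counts were 1, 1, 0, same, 23 and 1, and with both channels well above background the low-fat count was 6. The robust variance trend gave 0, 0, 0, same, 21 and 0. Array weights gave 116 at high fat, with Cyp1b1 at 1.67, 2 for wild-type diet, 4 for null diet and 199 for the mean, and turned the fatty acid synthesis list at high fat (0.34). The compared groups alone gave 0 at low fat, 0 for wild-type diet and 3 for null diet. The replicate block gave 1, 1, 0, same, 25 and 1 and changed no other gene count. Outside wild-type diet the numbers do not pair the arrays throughout. Correlations were -0.439, -0.0515 and 0.0226 at low fat, -0.0229, 0.571 and -0.00740 at high fat, and -0.303, -0.569 and 0.0858 for null diet. Same-numbered arrays shared a scan for replicates 1 and 2 at high fat and for replicate 3 in null diet. The slide block gave 1 at low fat, 0 for both diet responses, 11 for the mean and 1 shared, and turned the cytokine list at low fat (0.12) and in the mean (0.087), Ndufv1 for the interaction (0.082), Cfd in the mean (0.31) and the correlation of genotype at high fat with wild-type diet (0.0649). The scan block gave 14, 5, 0, same, 94 and 4, and 0.0583 for that correlation. The scan block without wild-type low-fat array 1 gave 22, 39, 2, 8, 138 and 10, with 10 lists for wild-type diet and 6 for the interaction, Cyp1b1 at 2.63 and 1.73 and that correlation at 0.134. It turned the cytokine (0.15), Kupffer (0.38), stellate (-0.13, in its test) and cell cycle (0.11) lists at low fat, the acute phase list for wild-type diet (-0.043, in its test), and the cytokine (0.061) and cell cycle (0.074) lists in the mean. With an estimated correlation 1, 2, 1, 0, 0 and 6 lists passed at low fat, high fat, wild-type diet, null diet, interaction and mean. With 1 array left out, genes numbered 1 to 26 at low fat, 0 to 5 at high fat, 0 to 1 for each diet response, 19 to 113 in the mean and 0 to 4 shared, and lists 10 to 15, 11 to 18, 9 to 18, 4 to 12, 6 to 16 and 12 to 19 in the same order as before. Cyp1b1 ranged from 1.96 to 2.60 at low fat and from 1.51 to 2.02 at high fat, and the 3 correlations from 0.153 to 0.492 (diet responses), 0.331 to 0.656 (genotype differences) and -0.263 to 0.0800 (genotype at high fat with wild-type diet, 0.0681 without null high-fat array 1). Single arrays turned the stellate list at low fat (-0.57 to 0.071) and oxidative phosphorylation in the interaction (highest 0.0066), both without wild-type low-fat array 1, and fatty acid synthesis at high fat (-0.26 to 0.20) without wild-type high-fat array 1. Cyp1b1 for wild-type diet (-0.22 to 0.42) and Nnt turned without wild-type low-fat array 2 (-0.087 and -0.13) or 3, or wild-type high-fat array 2. Over all alternatives, named genes kept direction and call 5255 times, lost the call 158 times, gained it 162 times and turned 26 times. Lists kept both 1973 times, lost the call 364 times and turned 14 times. A list's direction in these counts is that of camera's test against all other genes, so its median could change sign without being counted. At low fat the medians ran from -0.33 to 0.38 for fatty acid oxidation and from -0.56 to 0.23 for MHC genes, with the direction kept in all 28 settings. Normalisation between arrays by Aquantile leaves log ratios as they are, so it tests nothing here, although it is among those counts. For named genes in a comparison of 2 groups, 3 kinds of setting cannot turn a change. These are the robust variance trend, the compared groups alone and leaving out an array of another group. An estimated correlation cannot turn a list, and the authors' deposited table repeats log ratios of Agilent's processed signals. Part of the directions counted as kept was therefore fixed in advance. The cause was not tested for any of these changes, and probes near background, such as those of Moxd1, Cfd and Cyp1b1, limit what folds can be given.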

Other observations

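No tests were chosen here after a result was seen beyond those named above. Several of the lists passed in none of the comparisons. Targets of the aryl hydrocarbon receptor, which controls Cyp1 genes, had medians of -0.23 at low fat (adjusted p = 0.455 in limma's camera) and -0.18 at high fat (0.242) over 9 measured members. Genes of growth hormone, IGF and leptin signalling had medians of -0.04 and 0.12, endothelial markers -0.03 and 0.12, erythroid and neutrophil markers 0.01 and 0.10, pancreatic acinar markers 0.08 and 0.06, and hepatocyte secreted proteins 0.04 and 0.14. Genes that flank Cyp1b1 on chromosome 17 had medians of 0.05 and 0.04 over 23 measured members. In the genotype comparisons 1 member passed in each of 3 of these lists, adjusted over the list alone. Over both diets these were Gsta1 of the first list at -0.67 (SE 0.19, adjusted p = 0.0414, and 0.255 over all genes) and Qpct, which flanks Cyp1b1, at -0.74 (SE 0.18, adjusted p = 0.0327, and 0.164 over all genes). At low fat it was Amy2a5 of the acinar list at 0.89 (SE 0.23, adjusted p = 0.0272, and 0.350 over all genes).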
